A study of Nephotettix cincticeps with 8 samples.

How the data were processed

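Each of 8 deposited files holds the scanner output of 1 two-colour Agilent array. Per the labels, 400 ng of total RNA was labelled with Cy3 or Cy5, and each array carried an infected and an uninfected RNA. The intensity values per spot were extracted by the authors with Agilent Feature Extraction, version 9.5.3.1 per the file headers and version 9.5.1 per the submitters' processing notes. The same files hold Agilent's LogRatio, per the file headers a log10 ratio of the background-subtracted and dye-normalised Cy5 and Cy3 signals. The authors' deposited value table holds log10 values that differed from LogRatio by at most 0.00499, which is rounding. Each of its columns has a median of 0 and its direction is Cy5 over Cy3, so that arrays of opposite dye orientation have opposite signs there. Scale, centring and direction of that table were all settled by this comparison.

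The titles give the dye of each RNA. Every ratio was turned to infected over uninfected. The 2 arrays of a replicate carry the same 2 RNAs with dyes swapped, and were counted as 1 replicate. The labels call the 4 replicates biological, and nothing states that they came from separate groups of insects, so the p-values measure the spread between these 4 samples. The pairing of infected and uninfected RNA within a replicate comes from their hybridisation to the same arrays. A correlation of the paired single channels would share the array's own effects, so no separate check of the pairing was made from the values.

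Median spot signals and median local backgrounds were corrected with limma's normexp method at an offset of 50. The planned correction used mean signals, which were not used here because the files list medians. Ratios were normalised by loess within each array, with control spots and spots flagged as outliers (1 to 6 per array) given weight 0. Control spots and flagged spots were then left out, 15 probes spotted 6 times were averaged over their spots, and the 2 arrays of each replicate were averaged. Of 15133 probes, 10543 (69.7%) were tested: those with infected or uninfected RNA well above background, by Agilent's flag, on at least 1 array of at least 3 replicates. Adding the offset of 50 compresses the ratios of dim probes.

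The 4 replicate ratios of each probe were tested against 0 with limma (lmFit and eBayes, version 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The median standard error of a log2 ratio was 0.051. The turning of ratios, the averaging and the limma test were run on simulated normalised log2 ratios of the same layout. These had 10523 probes, of which 200 were changed. There 72% of the probes changed by 1.5-fold and 93% of those changed by 2-fold were recovered, and 9 of 174 calls were false. Background correction, loess and the filter were not simulated, and noise was independent between probes. Changes under 1.5-fold, which make up most real calls, were not covered. Figures were drawn with matplotlib 3.10.9.

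The rule for named probes was fixed before the data were examined. It takes up to 12 annotated genes per direction with the largest mean log2 ratio among probes past the threshold with the same sign in 4 of 4 replicates, filled up to 6 by unadjusted p where fewer than 6 pass. It adds the 2 members of each tested gene list with the smallest p. Of probes without a gene name it takes at most the 2 with the largest rise and the 2 with the largest fall past the threshold, and this last part is the one that applied. The files pair no ID with a name, since the column for a systematic name repeats the ID. The 25 gene lists fixed beforehand covered immune effectors and signalling, chaperones, metabolism, cell division, bacterial sequences and markers of ovary, gut, fat body, muscle, salivary gland and nervous system. Of these lists 0 matched any probe and none was tested. Probes were instead grouped by the letters of their IDs, of which there are 14 kinds and whose meaning is not given in the sources used here. These groups were tested with camera, at a preset correlation of 0.01 and at an estimated one, and with fry. Reading IDs that differ in their last number as 2 probes of 1 transcript is an assumption.

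All 8 arrays lie on 1 slide in 2 rows, with replicates 1 and 2 in row 1 and replicates 3 and 4 in row 2, so the row was tested as a batch. The alternatives were Agilent's own log ratio, no background subtraction, an offset of 0, median centring, quantile normalisation of average intensities, no filter and a stricter filter on dim probes, and flagged spots kept. Further alternatives were a fit of the 8 arrays with a dye term, each dye orientation alone, the slide row as a term, unpaired single channels, leaving out each replicate, a 2-fold limit, and the authors' deposited value table. Fits within each slide row and the grouping by ID letters were added after the data were seen.

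The floored folds and the lower bounds of folds use normalised single-channel levels. The dim RNA of each array is set to the higher of its own signal and the lowest signal well above background. That lowest signal is taken over all non-control spots of the array. A signal not well above background can therefore lie over it and stay unraised, so the floor can act weakly. Each such fold is a mean over the 4 replicates, so single replicates can lie below it. The intervals of medians in the closing section come from resampling ID stems, and those of shares are exact binomial intervals at 95%. The binomial intervals treat probes or stems read on the same arrays as independent, so they may be too narrow.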

Results

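Gene expression was measured in abdomens of adult females of the green rice leafhopper *Nephotettix cincticeps*, a sap-feeding insect of rice, that carried or did not carry *Rickettsia*, an intracellular bacterium. The females were 1 day into adulthood and came from a laboratory strain in which infected and uninfected individuals occur together. Infection had been typed by PCR on DNA from the head and thorax, and RNA was taken from the abdomen of the same insects. Each of 8 arrays of 1 slide carried an infected and an uninfected RNA in different dyes. The arrays formed 4 biological replicates, each hybridised in both dye orientations, so that n = 4 for every comparison. The labels mention 5 insects of each kind and do not say whether each extract pooled them.

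The arrays held 15133 probes under 9195 ID stems, where a stem is the probe ID without its last number. The files pair no probe with a gene name, so probes are given by ID, and the changes below are not assigned to pathways. Between 62.8% and 73.6% of the probes were well above background in an RNA on a single array, and 0 spots were saturated. The number of replicates limits the precision. The log2 ratios of infected to uninfected RNA correlated across probes with r between 0.794 and 0.837 within the 4 dye-swapped pairs. Between replicates, after averaging the pairs, r lay between 0.391 for replicates 2 and 3 and 0.683 for replicates 3 and 4. Probes are not independent replicates, so these values describe the arrays. The log2 ratios had an SD across probes of 0.371 in replicate 1, 0.451 in replicate 2, 0.372 in replicate 3 and 0.383 in replicate 4.

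The comparison asked which transcripts of the female abdomen differ in level between *Rickettsia*-infected and uninfected insects. The largest differences were falls at 2 ID stems, whose signal in infected abdomens was close to background. Where the dimmer RNA was not above background on every array, a floored fold is given. It is the mean fold over replicates after dim signals were raised to the lowest signal well above background. Single replicates can lie below it, and where the floor raised nothing it equals the measured fold. Probe NC_EB0496-1 was 378-fold lower in infected abdomens, both as measured (378.2) and after flooring (377.8). The floor hardly acted on it, so flooring was no safeguard against background here. The measured log2 ratio of this probe was -8.56 ± 0.20 (SD, n = 4; limma adjusted p = 4.14e-06). Its infected RNA was well above background on 4 of 8 arrays and its uninfected RNA on 8, and the log2 ratio ran from -11.3 to -8.37 across the alternatives. The other probe of that stem was 159-fold lower after flooring, at a measured -7.31 ± 0.10 (SD, n = 4; limma adjusted p = 1.56e-06), with infected RNA above background on 5 arrays. Probe NC_EB1704-1 was 189-fold lower both as measured and after flooring, at -7.56 ± 0.33 (SD, n = 4; limma adjusted p = 3.38e-05). Its infected RNA was above background on 6 of 8 arrays, and its log2 ratio ran from -9.20 to -7.16 across the alternatives. The other probe of its stem was 19.5-fold lower after flooring, at a measured -4.41 ± 0.36 (SD, n = 4; limma adjusted p = 0.000562), with infected RNA above background on 1 array.

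The 2 largest rises were smaller and less even between replicates. Probe NC_Bac3843-1 was 18.6-fold higher in infected abdomens, at 4.22 ± 1.02 (SD, n = 4; limma adjusted p = 0.00628), with replicate values of 4.86, 4.92, 4.36 and 2.74. Its log2 ratio was 4.89 within slide row 1 and 3.55 within row 2, the ends of its range across the alternatives. The other probe of this stem, also above background in both RNAs on all 8 arrays, was 1.26-fold higher, at 0.34 ± 0.09 (SD, n = 4; limma adjusted p = 0.0141). Probe NC_NY2307-1 was 6.29-fold higher after flooring, at a measured 2.71 ± 1.12 (SD, n = 4; limma adjusted p = 0.0169). Its replicate values were 1.94, 1.94, 2.63 and 4.31. The log2 ratio ran from 1.94 to 4.01 across the alternatives, with 1.94 within slide row 1 and 3.47 within row 2. Its uninfected RNA was above background on 6 of 8 arrays, and no other probe of its stem was tested. With Agilent's own log ratio it was higher by 4.01 ± 2.71 (SD, n = 4) on the log2 scale, and the call ended at a limma adjusted p of 0.0694 (range 0.000691 to 0.0694 across the alternatives) because the spread grew more than the mean.

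**Figure D1:**
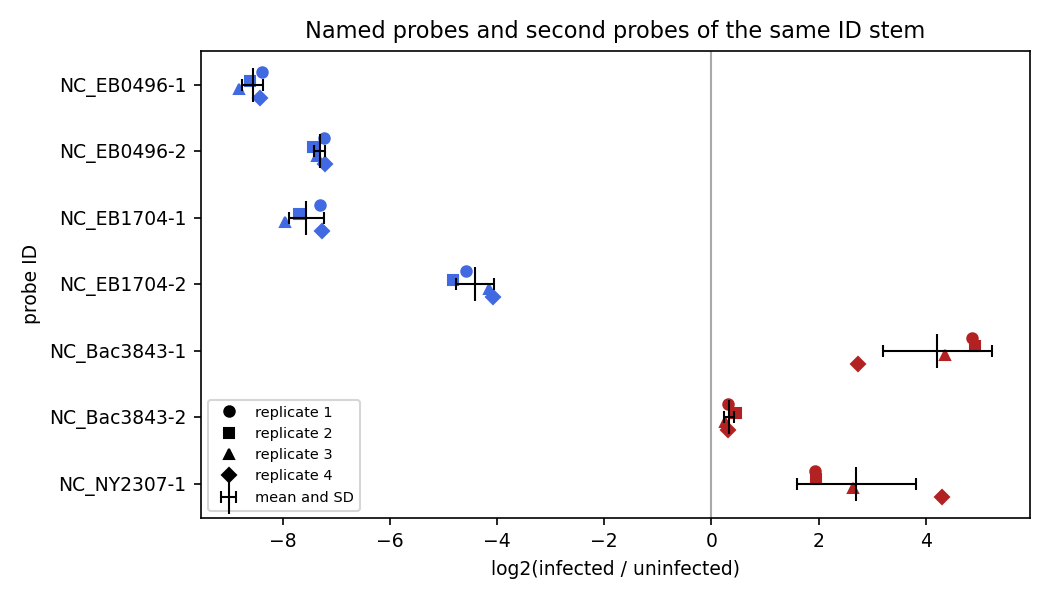
Log2 ratio of infected to uninfected RNA (horizontal axis) in each of the 4 biological replicates for the named probes and the other tested probe of the same ID stem, with the mean and SD over replicates. Both probes of NC_EB0496 and of NC_EB1704 lie below -4 in every replicate, while NC_Bac3843-1 has a mean of 4.22 and NC_Bac3843-2 of 0.34.

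Across the array, many small differences accompanied these few large ones. Of 10543 probes tested, 1032 (9.79%) were higher and 1172 (11.1%) were lower in infected abdomens at an adjusted p below 0.05 (limma with Benjamini-Hochberg adjustment, two-sided). They belong to 778 and 828 ID stems. Most differences were small: 82.3% of the 2204 called probes changed by less than 1.5-fold, and the median was 1.25-fold in either direction. At least a 2-fold difference was found for 56 of the higher and 57 of the lower probes, and at least a 4-fold difference for 16 and 11. A difference of at least 16-fold was found for 1 higher probe, NC_Bac3843-1, and for 7 lower probes. All 2204 called probes had the same sign in 4 of 4 replicates, which the threshold nearly requires with 4 values. Of all tested probes 47.6% had the same sign in 4 of 4, against 12.5% by chance if the replicates are independent. The labels do not state that they came from separate insects.

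The counts depend on which replicates enter and on the pairing of the RNAs. They fell to 365 higher and 356 lower without replicate 1, to 265 and 258 without replicate 2, to 699 and 838 without replicate 3 and to 232 and 227 without replicate 4. Without the replicate block, treating the paired RNAs as independent samples, they were 569 and 607, and with the row of the slide as a term they were 845 and 992, with 8 and 7 within row 1 and 119 and 119 within row 2 (n = 2 replicates per row).

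**Figure D2:**
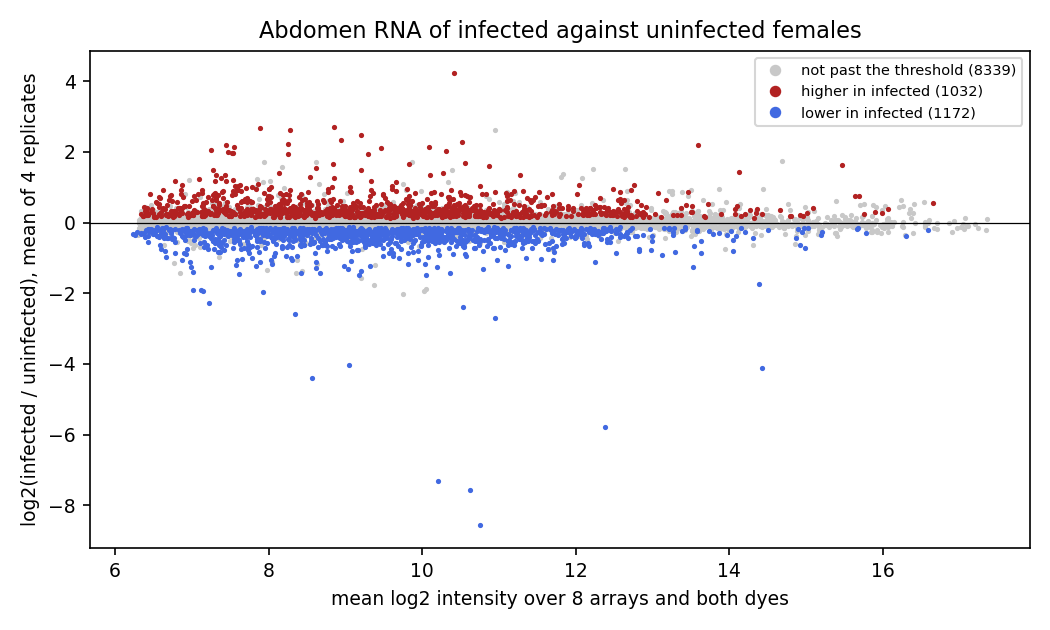
Mean log2 intensity of each tested probe (horizontal axis) against its mean log2 ratio of infected to uninfected RNA over 4 replicates (vertical axis). Red points are the 1032 probes called higher and blue points the 1172 called lower, and most of both lie close to 0, with 7 blue points at least 16-fold below it.

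Some probes were above background in a single kind of RNA. On all 8 arrays, 8 probes were well above background in uninfected RNA and not well above background in infected RNA. All 8 were called lower, which choosing them in this way makes likely. For these the uninfected level was at least 1.56-fold to at least 4.02-fold the infected level, depending on the probe. In the other direction, 5 probes were above background in infected RNA alone, and their bounds ran from at least 1.46-fold to at least 4.37-fold. All 5 were called higher, which their choice likewise makes likely. The bound sets the mean normalised log2 level of the brighter RNA against the higher of the dim signal and the lowest signal well above background.

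For 4461 ID stems 2 probes were tested, which gave a second measurement within each stem. Across stems the log2 ratios of the 2 probes correlated with r = 0.750 and rho = 0.789. Both probes were called higher in 254 stems and lower in 344, and they were called in opposite directions in 17. In 672 stems 1 of the 2 probes was called, and in 559 of these the other probe had the same sign. Among 73 stems with a probe called at 2-fold or more, both probes were changed by at least 2-fold in the same direction in 17, of which 10 were lower and 7 higher in infected abdomens.

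**Figure D3:**
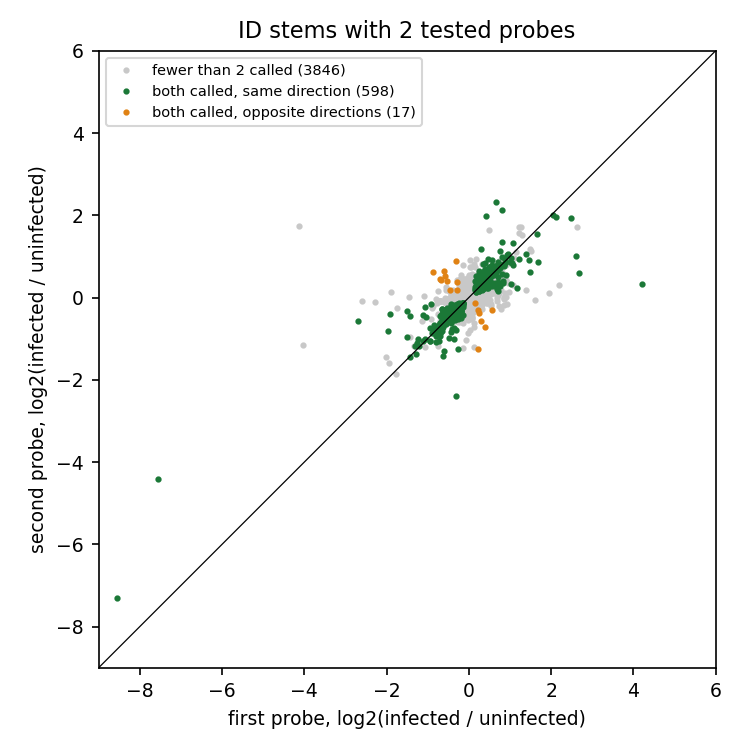
Log2 ratio of infected to uninfected RNA of the first (horizontal axis) and second probe (vertical axis) of each of 4461 ID stems, with the line of equal values. In 17 stems, drawn in orange, the 2 probes were called in opposite directions.

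Some probes, most with the letters MG in their ID, differed strongly between replicates. Of 130 probes whose log2 ratio had an SD over 1 between the 4 replicates, on the arrays with infected RNA in Cy5, 83 carried these letters. NC_Bac3843-1 and NC_NY2307-1 are among the 130, of which 7 were called. The 83 MG probes were 8.41% of the 987 MG probes tested, against 47 of 9556 other probes (0.492%). The median log2 ratio of the 83 probes was 0.18 in replicate 1, 1.83 in replicate 2, -1.58 in replicate 3 and -0.18 in replicate 4, and limma called 0 of them (7 had an unadjusted p below 0.05). Choosing probes for a large SD between replicates makes a call unlikely. The counts of calls among them therefore do not tell whether they respond to infection. Over the tested probes without MG letters the correlation between replicates 2 and 3 was 0.704, against 0.391 over all. This group of probes was chosen after its values were seen, because they differed between replicates, so their removal raises that correlation by construction.

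**Figure D4:**
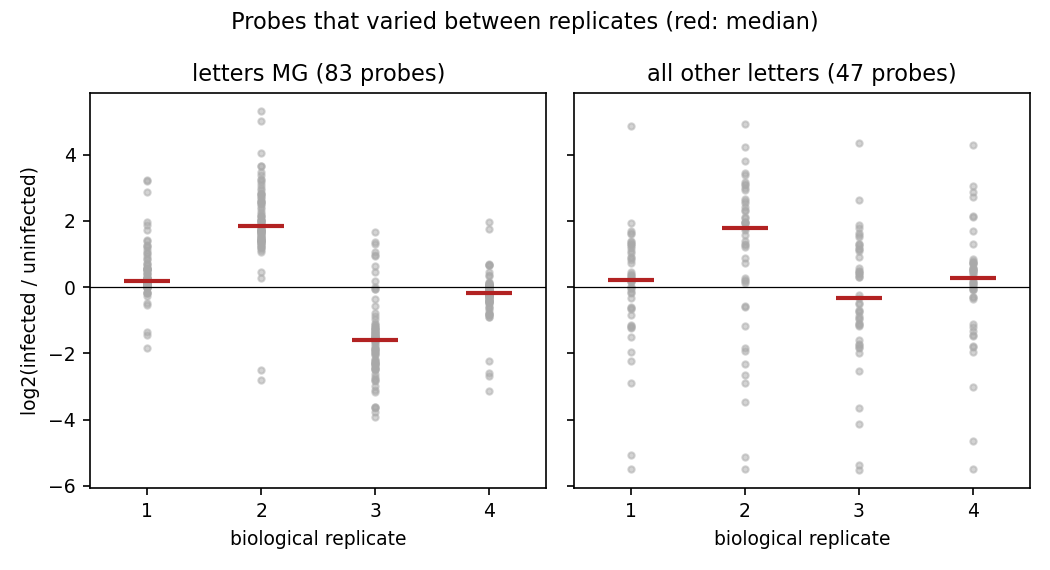
Log2 ratio of infected to uninfected RNA (vertical axis) in each biological replicate (horizontal axis) for the 130 probes that varied most between replicates, 83 with the letters MG (left) and 47 with other letters (right). Points are probes and red bars medians, and the MG probes have a median of 1.83 in replicate 2 and -1.58 in replicate 3.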

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

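The tests in this part were chosen after the result was seen. The spread of the log2 ratios across probes was 0.451 in replicate 2 against 0.371, 0.372 and 0.383 in the other replicates, and the gap between replicate 2 and the nearest of these took up 0.848 of the whole range. Of 17 sets of 4 values tested in this way, 1 stood out, and chance alone flags about 1 set in 20. Over the probes without the letters MG in their ID the spreads were 0.368, 0.404, 0.331 and 0.383 in replicates 1 to 4. Replicate 2 still had the widest, and its gap took up 0.296 of the range. The MG probes were singled out because they differ between replicates, so this comparison is no test of the cause.

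A set of 130 probes, 83 of them with the letters MG, differed strongly between replicates. Noise of single hybridisations is argued against: in 127 of the 130 probes (97.7%, 95% interval 93.4% to 99.5%) the replicate with the highest ratio was the same in both dye orientations, against 25% by chance and 54.3% of the other probes. A fault of single probes is argued against too, since in 67 of 73 ID stems (91.8%, 95% interval 83.0% to 96.9%) both probes had the same highest replicate. Many of these probes share a profile over the replicates, so both intervals may be too narrow. For the 83 MG probes the median level in infected RNA lay 1.23 above each probe's mean in replicate 2 and -0.88 from it in replicate 3 on the log2 scale, while in uninfected RNA it lay at -0.60 and 0.77. A difference between the RNA extracts stays open, and it may come from the insects or from how much of each tissue an extract held, neither of which was tested.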

How the results depend on the processing

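The alternatives were chosen before the data were examined, except the fits within slide rows. Leaving out quantile normalisation of average intensities, which moves no ratio, and the authors' value table, which repeats Agilent's log ratio, 11 of 19 alternatives gave counts within 1.5 times the 1032 higher probes and 12 within 1.5 times the 1172 lower ones. Outside this range, the arrays with infected RNA in Cy5 alone gave 1727 higher probes, against 1079 with it in Cy3 alone. In a fit of 1 orientation a dye effect adds to the ratio, while the main fit averages both orientations. Between arrays of different replicates, r was 0.395 to 0.697 in the same dye orientation and 0.283 to 0.560 in opposite orientations. Whether a dye effect explains the count of 1727 was not tested. Fewer samples or a higher limit gave fewer calls: 8 higher and 7 lower within slide row 1, 119 and 119 within row 2, and 56 and 57 at 2-fold or more. Without the replicate block, as unpaired RNAs, there were 569 higher and 607 lower probes. Leaving out 1 replicate gave 232 to 699 higher and 227 to 838 lower probes, with 365 and 356 without replicate 1, 265 and 258 without replicate 2 and 232 and 227 without replicate 4. All 2204 called probes had the same sign in 4 of 4 replicates, so leaving replicates out cannot turn a sign. Of them 2182 kept their sign with infected RNA in Cy5 alone and 2131 with it in Cy3 alone. The share of lower among called probes was 53.2%, and 47.9% and 57.0% in these 2 fits. NC_EB0496-1, NC_EB1704-1 and NC_Bac3843-1 passed the threshold under every alternative that tested them. NC_NY2307-1 missed it with Agilent's own log ratio (log2 4.01, adjusted p = 0.0694) and with the authors' value table (adjusted p = 0.0693), and passed in 17 of 19. The gene list shift and its alternatives were not run, because no probe has a name. Signal over background limits the ratios of dim RNAs: NC_EB0496-1 was at -8.56, and at -9.78 with an offset of 0.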

Other observations

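The tests of dye bias, of the second probe, of the stems parted by their calls and of the sign patterns of the replicates, and the grouping by ID letters, were chosen after the results were seen. The letters of the IDs make 14 groups, and the 4 with the largest difference between their counts of higher and lower probes are given here, chosen after the counts were seen. Of 1373 probes with the letters MYA, 274 were lower in infected abdomens (20.0%) and 102 higher (7.43%), and of 2757 with OV, 344 were lower and 210 higher. More probes were higher than lower for EB, with 170 and 109 of 1135, and for MG, with 103 and 57 of 987. The counts themselves were not tested. Of the 14 groups 0 passed camera after adjustment at the preset correlation (lowest adjusted p = 0.199). There 2 groups had an unadjusted p under 0.05: OV, and NY with 54 higher and 25 lower of 345 probes. At an estimated correlation 0 groups passed camera (lowest adjusted p = 0.668), and 0 had an unadjusted p under 0.05. With fry 0 passed (lowest adjusted p = 0.205), and 1 group, CCB, had an unadjusted p under 0.05.

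With the pairing taken out, 1 of the 35 splits of the 8 RNAs into 4 and 4 gave as many called probes as infection did, namely the real split with 1176. The highest other split gave 371, and it sets replicates 1 and 2 against replicates 3 and 4, which is the split by row of the slide and parts 0 pairs. With the row as a term the paired fit called 845 higher and 992 lower probes. Among the 8 splits that part all 4 pairs, as the real one does, the highest other gave 0, and 8 splits are too few for a share under 0.05. For the paired count of 2204, 1 of the 8 sign patterns of the replicates, the real one, gave as many, and the highest other gave 2. With 8 patterns no share under 0.05 can be reached.

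The changes of at least 2-fold are the pattern a biologist would follow up first. Dye bias is argued against: of 133 probes called at 2-fold or more on the arrays with infected RNA in Cy5 alone, 0% had the opposite sign on the other arrays (exact 95% interval up to 2.74%), nor did any of 119 chosen the other way round (0%, up to 3.05%), and the other orientation showed a median of 0.926 and 0.992 of the log2 change. Changes under 2-fold were not covered by this test of dye bias. For part of the changes of at least 2-fold, a sequence difference under a single probe, between the infected and uninfected insects of the strain, stays open. No sequence was examined. The other probe of the stem showed a median of 0.583 of the log2 change for falls (95% interval 0.284 to 0.880, 51 probes). For rises it showed 0.664 (0.317 to 0.800, 39 probes), and both intervals are too wide to decide. Among falls the other probe showed more than 0.5 of the change for 26 probes and less than 0.25 for 17, and among rises for 23 and 9, and choosing probes for their size pulls these ratios down. A hereditary difference between infected and uninfected insects stays open beside an effect of infection, because the labels do not say whether the 2 kinds share parents.

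In 39 ID stems the ratios of the 2 probes differed at least 2-fold, and in 17 of these the signs were opposite. The widest gap among stems whose difference between probes passed a limma test of its own, singled out after its values were seen, was in NC_MYA4936 (limma adjusted p of the difference = 0.0278): -4.12 ± 1.39 (SD, n = 4; limma adjusted p = 0.0115) for one probe and 1.74 ± 1.33 (SD, n = 4; limma adjusted p = 0.0666) for the other, which was not the dimmer one (mean log2 intensity 14.7 against 14.4). A dim second probe compressed towards 0 is argued against for the 8 stems whose probes both passed the threshold in opposite directions, since compression cannot turn a sign. For the other 31, of which 9 have opposite signs with at least 1 probe not called, it stays open as a group, because the less changed probe was the brighter one in 67.7% of them (exact 95% interval 48.6% to 83.3%), and in 59.0% of all 39 (42.1% to 74.4%), too few stems to decide. Transcript forms or sequences that differ between the infected and uninfected insects stay open and were not tested.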
